A study of Oryza sativa with 2 samples.

How the data were processed

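Gene expression was measured in rice (Oryza sativa) with an oligonucleotide array that carried SuperSAGE tags. SuperSAGE is a sequencing method that represents each transcript by a short tag taken from near its 3′ end. Per the series' design text, the oligonucleotides were synthesized directly on the chip, were 26 bases long and matched the tags exactly. Of the 2 arrays, 1 was hybridised with RNA from mature leaf and 1 with RNA from suspension-cultured cells, which are undifferentiated rice cells kept dividing in liquid medium. Per the labels' protocols, total RNA was copied into double-stranded cDNA from an oligo-dT primer with a T7 promoter, transcribed in vitro into biotin-labelled cRNA and fragmented before hybridisation. Each array therefore had 1 colour.

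The values used were the authors' deposited intensities, 1 per feature and array, on a linear scale. The submitters' processing notes name RMA, a method that corrects background, equalises probe distributions between arrays and summarises probes. Its version and settings, the number of probes behind each feature, and any later scaling are not given in the sources used here. RMA usually returns log2 values. The deposited values reached 60143, and none was exactly a whole number, with no tolerance allowed, so they were taken as linear intensities. Quantile equalisation of the summarised values was not evident, since the quartiles of the 2 arrays differed. The table had 1000 features and 0 missing values, with no detection calls, no control features marked as such and no background readings. The lowest values on each array are therefore a floor of unknown relation to background, and ratios of features near that floor depend on it. RMA can also compress or stretch ratios at low intensity.

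Feature identifiers had 3 prefixes, OsL, OsSC and Osconst, each followed by a number. The meaning of the prefixes and of the numbers is not given in the sources used here. Neither the tag sequences nor gene names were paired with the identifiers in the table. Matching the identifiers to the gene identifiers, symbols, synonyms and accessions of 39387 genes of the rice assembly ASM3414082v1 gave 0 matches. No gene is therefore named. The 22 gene lists fixed before the data were examined, among them lists for photosynthesis, ribosomal proteins, defence, the cell cycle and leaf cell types, had no member on the array that could be recognised, so no list has a result. The 3 identifier classes were compared in their place, a choice made after the table was seen. If the classes were chosen from tag counts in these same tissues, which the sources used here do not say, their direction is not independent evidence of a difference between leaf and cells.

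Log2 intensities were computed without a pseudocount, and the difference was taken as leaf minus suspension cells. With 1 array per group there was no replicate, so no p-value, standard error or test between leaf and cells was computed, and every difference describes these 2 arrays. The number of arrays, not the number of features, limits the precision. Sample and array cannot be told apart. Features at least 2-fold apart were counted by that fixed rule of size. Each class median was ranked among the medians of 10000 random lists of the same size, drawn from all 1000 features and matched on mean log2 intensity in 10 bins. Intervals of medians and of rank correlations came from 2000 bootstrap resamples of features and cover 95% of them. They describe how much a median or correlation changed when the features were resampled, and not the range of the features. Features are not independent replicates, so the intervals carry no error between samples. The rule for named items, set beforehand, took the largest differences among features at or above the median of mean log2 intensity. Since the features carry no gene names, 2 identifiers are printed in each direction.

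The alternatives were centring on the median of all features or on the Osconst median, quantile normalization, removal of a loess curve on mean level with a span of 0.4, a pseudocount of 16, 2 filters on dim features, thresholds of 3-fold and 1.5-fold, and a floor at each array's lower quartile. Centring on Osconst and the floor were added after seeing the data. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures from matplotlib 3.10.9. They were tested on simulated data made from the 1000 mean levels, with noise of SD 0.25 added to each log2 value. The 2-fold rule recovered 94% of 100 features changed by 1.5 on the log2 scale and 100% of 100 changed by 3, and picked 4 of 800 unchanged features. That noise was assumed, since the noise of these arrays is unknown.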

Results

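The data were 1000 tag intensities from 1 array of rice mature leaf and 1 array of suspension-cultured rice cells. Of the features, 438 carried the prefix OsL, 484 the prefix OsSC and 78 the prefix Osconst. The median intensity was 1181 on the leaf array and 1153 on the cell array. The middle of the distribution spanned 286.3 to 4752 (lower to upper quartile) on the leaf array and 234.4 to 4347 on the cell array. Intensities ran from 76.5 to 60143 in leaf and from 58.4 to 51275 in cells. There was no replicate of either sample, so no difference below could be set against replicate error.

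The question put to these arrays by the series title was how gene expression in mature leaf compares with that in cultured cells. On the deposited values, 257 features (25.7%) were at least 2-fold higher in leaf, 324 (32.4%) were at least 2-fold higher in suspension cells, and 419 (41.9%) lay within 2-fold. That last group held most of the 118 features at or below the lower quartile of both arrays, of which only 7 were at least 2-fold apart. Whether these had signal over background is unknown, so lying within 2-fold does not show like expression for them. Differences of at least 8-fold were seen for 162 features towards leaf and 98 towards cells, so the larger differences ran more often towards leaf although the 2-fold differences ran more often towards cells. Of these, 161 towards leaf were OsL features and 95 towards cells were OsSC features. The balance of such counts therefore depends on which tags the array carried, and not only on the samples. Across features, log2 intensities on the 2 arrays had a Pearson correlation of 0.30 and a Spearman correlation of 0.31. Without the features in the lowest 25% of mean level, the Pearson correlation turned to -0.10 and the Spearman correlation was 0.0026, but selecting features on the mean of the arrays lowers their correlation by construction. Within each class the Pearson correlation was higher than over all features, 0.41 in OsL, 0.61 in OsSC and 0.87 in Osconst. The value over all features thus also depends on which tags the array carried. These correlations are across features of a single pair of arrays, and features are not independent replicates.

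The balance of the 2-fold counts depended on how the arrays were scaled to each other. The median difference over all features was -0.25 on the log2 scale (leaf minus cells). Features higher in leaf made up 44.2% of those at least 2-fold apart as deposited. When differences were centred on the median of the Osconst features, an alternative chosen after seeing the data, 361 features were at least 2-fold higher in leaf and 210 in cells, and the leaf share became 63.2%. Such centring shifts all differences alike, so it moves the balance by construction. Quantile normalization kept more features towards cells, with 251 towards leaf and 343 towards cells, and loess gave 299 and 257. The excess of 8-fold differences towards leaf held under each scaling, from 155 against 103 after quantile normalization to 198 against 62 when centred on Osconst.

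**Figure D1:**
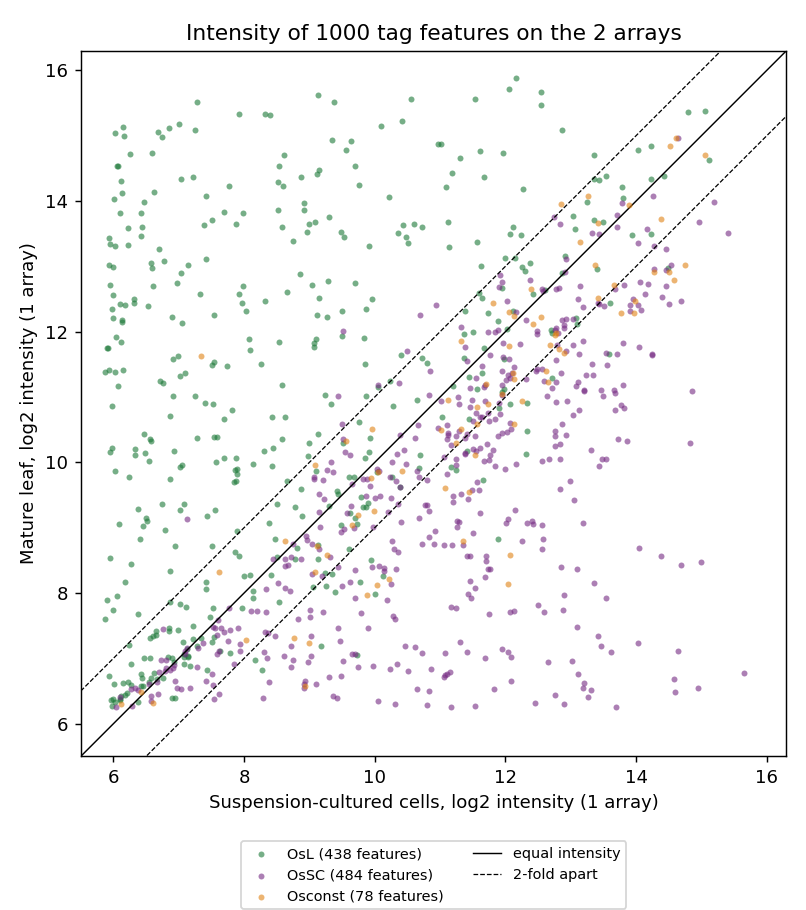
Log2 intensity of each of the 1000 features on the leaf array (vertical axis) against the suspension cell array (horizontal axis), with 1 point per feature coloured by identifier class, a solid line of equal intensity and dashed lines at a 2-fold difference. Above the upper dashed line lie 246 OsL, 9 OsSC and 2 Osconst features, and below the lower one 25 OsL, 274 OsSC and 25 Osconst features.

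The OsL features were the group with higher signal in leaf. Their median intensity was 2519 on the leaf array and 308.5 on the cell array. The median difference was 1.78 on the log2 scale, a 3.43-fold higher signal in leaf, with quartiles of 0.18 and 4.28. It was 2.03 above the median of all features. Of the 438 OsL features, 246 (56.2%) were at least 2-fold higher in leaf, 25 (5.71%) were at least 2-fold higher in cells and 167 lay within 2-fold. The counts were 269 towards leaf and 15 towards cells after loess, and 318 and 9 when centred on the Osconst median. All but 1 of the 162 features at least 8-fold higher in leaf were OsL features. The OsL median lay above the medians of all 10000 random lists matched on mean intensity, whose central 95% ran from -0.31 to -0.05. Those lists were drawn mostly from OsL and OsSC features, which leaned opposite ways, so such a rank follows largely from that split.

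The OsSC features had the strongest lean towards suspension cells, and the Osconst features leaned the same way less strongly. The median intensity of OsSC features was 698.0 in leaf and 2747 in cells. The median difference was -1.29, a 2.44-fold higher signal in cells, with quartiles of -2.55 and -0.38. Relative to the median of all features it was -1.04. Of the 484 OsSC features, 274 (56.6%) were at least 2-fold higher in cells, 9 (1.86%) were at least 2-fold higher in leaf and 201 lay within 2-fold. OsSC features accounted for 95 of the 98 that were at least 8-fold higher in cells, and for 0 of those at least 8-fold higher in leaf. The OsSC median lay below the medians of all 10000 matched random lists, whose central 95% ran from -0.46 to -0.17. This rank mirrors that of OsL, since both classes made up most of the pool, and is not separate support. With differences centred on the Osconst median, the OsSC median was -0.55, 191 OsSC features were at least 2-fold higher in cells and 32 in leaf. The count towards leaf was 23 after loess and 16 when centred on the median of all features.

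The Osconst features varied least between the samples. Of the 78, 51 (65.4%) lay within 2-fold, against 38.1% of OsL and 41.5% of OsSC features. These shares include features dim on both arrays: at or below both lower quartiles were 68 OsL, 47 OsSC and 3 Osconst features, few of them 2-fold apart. The SD of the differences over features was 1.11 in Osconst, 2.71 in OsL and 1.85 in OsSC. The Pearson correlation of log2 intensities between the arrays was 0.87 within Osconst, 0.61 within OsSC and 0.41 within OsL. The Osconst features were not centred on equal intensity. Their median difference was -0.74, a 1.67-fold higher signal in cells, and 58 of the 78 had the higher value in cells. The median stayed below 0 after centring on all features (-0.49), quantile normalization (-0.79) and loess (-0.25). At least 2-fold differences were seen for 25 of them towards cells and 2 towards leaf. That split was 22 and 5 when centred on the median of all features, 17 and 7 after loess, and 10 and 11 when centred on the Osconst median itself. The Osconst median lay at percentile 4.1 of the matched random lists, whose central 95% ran from -0.77 to 0.15 and so included it. It lay outside the central 95% when lists were not matched on mean intensity (percentile 1.7) or when means replaced medians (percentile 0.28). The lists were drawn mostly from OsL and OsSC features, so these ranks set Osconst against that mix. Over all features the mean difference was 0.16 and the median -0.25, so means and medians set Osconst against different levels.

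**Figure D2:**
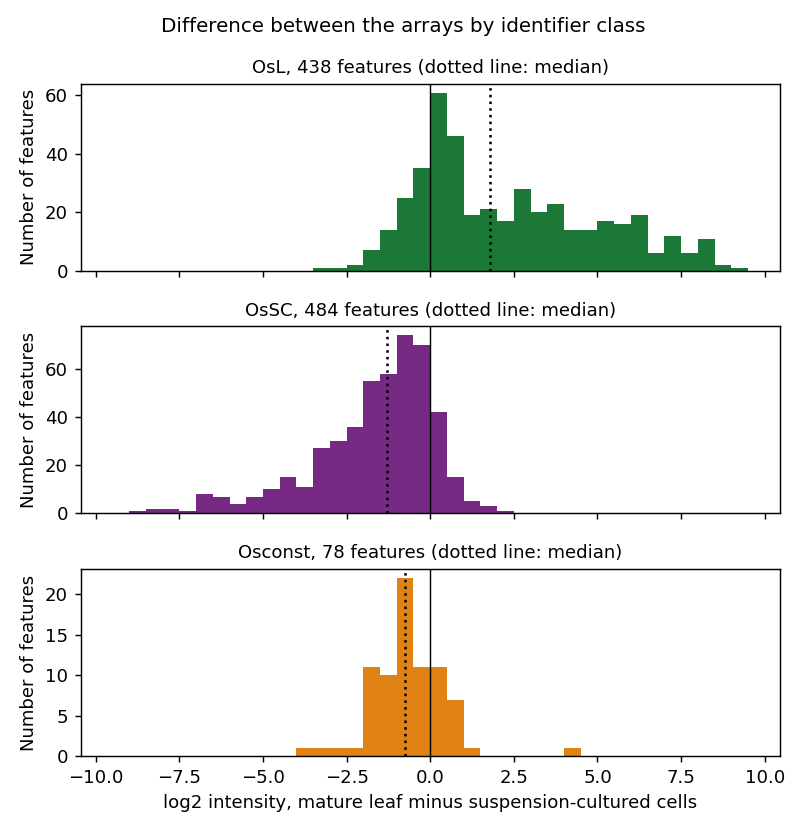
Number of features (vertical axis) by log2 intensity difference, leaf minus suspension cells (horizontal axis, bins of equal width), for each identifier class, with a solid line at 0 and a dotted line at the class median. The medians are 1.78 for OsL, -1.29 for OsSC and -0.74 for Osconst, and the OsL and OsSC distributions have long tails in opposite directions.

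Some features were bright in a single sample. At or above the upper quartile of the leaf array and at or below the lower quartile of the cell array there were 57 features, all of them OsL, with a median difference of 7.09. The reverse, at or above the upper quartile in cells and at or below the lower quartile in leaf, held for 29 features, all of them OsSC, with a median difference of -6.32. If the arrays were unrelated, 62.5 features would be expected in each such set. Another 108 features were at or above the upper quartile of both arrays, of which 39 were OsL, 47 OsSC and 22 Osconst. At or below the lower quartile of both arrays were 118 features, of which 68 were OsL, 47 OsSC and 3 Osconst. Of these 118, 5 were at least 2-fold higher in leaf and 2 in cells, and whether their signals exceeded background is unknown. Probes differ in how strongly they bind, so these sets describe signal and not transcript abundance.

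Among features at or above the median of mean log2 intensity, the largest difference towards leaf on the deposited values was that of OsL38, with an intensity of 33510 in leaf and 65.0 in cells, a log2 difference of 9.01. OsL204 followed with 35964 in leaf and 71.0 in cells, a log2 difference of 8.98. Towards cells, OsSC13 had 51275 in cells, the highest intensity on that array, and 109.9 in leaf, a log2 difference of -8.87. OsSC19 had 31700 in cells and 93.3 in leaf, a log2 difference of -8.41. In each case the dimmer value lay near the lowest values of its array, so the size of the ratio depends on that floor, whose relation to background is unknown. With values under each array's lower quartile raised to that quartile, the log2 differences were 7.16 for OsL38, 7.26 for OsL204, -7.48 for OsSC13 and -6.79 for OsSC19. The order towards leaf then changed, with OsL204 at rank 4 and OsL38 at rank 8, while OsSC13 and OsSC19 stayed the first and second towards cells. The genes behind these tags are not named here, because the table does not pair identifiers with sequences or genes.

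Within OsL and OsSC, features with low identifier numbers differed more between the samples. The 55 OsL features with the lowest numbers had a median difference of 5.52, and 52 of them were at least 2-fold higher in leaf. The 55 with the highest numbers had a median difference of 0.25, and 15 were at least 2-fold higher in leaf. Median leaf intensity was 17211 in the first set and 943.7 in the last, and median cell intensity was 185.8 and 780.8. The 61 OsSC features with the lowest numbers had a median difference of -2.39, and 48 of them were at least 2-fold higher in cells. Among the 61 with the highest numbers the median was -0.84, and 29 were at least 2-fold higher in cells. The course between them was uneven, with medians of -1.23, -1.57, -1.33, -1.15, -0.72 and -1.27 in the sets of consecutive numbers from the second to the seventh. Median leaf intensity was 431.1 in the first OsSC set and 551.3 in the last, and median cell intensity was 4174 and 1212. What the numbers order is not given in the sources used here.

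**Figure D3:**
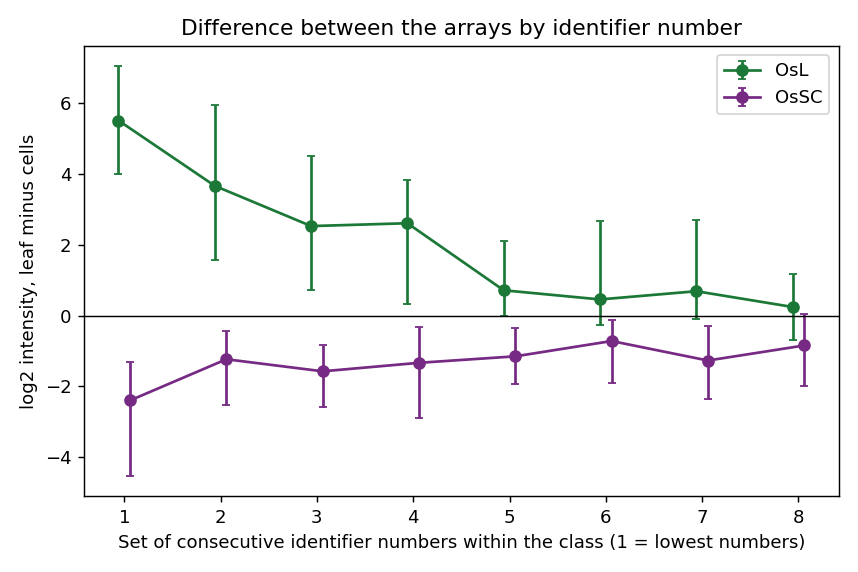
Median log2 intensity difference, leaf minus suspension cells (vertical axis), over OsL and OsSC features put in 8 sets of consecutive identifier numbers (horizontal axis, set 1 with the lowest numbers), with bars from the lower to the upper quartile over features. The OsL median goes from 5.52 in the first set to 0.25 in the last, and the OsSC median from -2.39 to -0.84.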

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

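No result was tested against replicates, so stability here means only that a value kept its sign or that a count stayed within 1.5 times; centring on Osconst, the floor at the lower quartile and every setting for the classes were chosen after seeing the data. Towards leaf the 2-fold count (257) ran from 212, without the lowest 25% of mean level, to 361. Towards cells (324) it ran from 210 to 343, with 422 at 1.5-fold. Of these, only 210, centred on the Osconst median, moved by over 1.5 times. On linear values the Pearson correlation was 0.19. Without the features in the lowest 25% of mean level it turned to -0.10, and the Spearman correlation fell to 0.0026. Selecting features on the mean of the arrays lowers their correlation by construction, so this is no measure of instability. The 3 class medians kept their signs under each setting run. For OsL the median was 2.03 centred on all features, 2.52 centred on Osconst, 1.58 after quantile normalization, 1.97 after loess, 2.78 without the lowest 25% of mean level, 2.59 without features in the lowest 25% on both arrays, 1.67 with the pseudocount and 1.29 with the floor, and the mean was 2.34. For OsSC, in the same order, the values were -1.04, -0.55, -1.41, -0.85, -1.47, -1.49, -1.27 and -1.10, with a mean of -1.69 and a median of -1.28 without its largest member. For Osconst they were -0.49 centred on all features, -0.79 after quantile normalization, -0.25 after loess, -0.75 without features in the lowest 25% on both arrays, -0.71 with the pseudocount and -0.70 with the floor, with a mean of -0.68. The cause of these shifts was not tested. The Osconst median stood at percentiles from 0.28 (mean in place of median) to 8.41 (without the lowest 25% of mean level) of random lists. OsL and OsSC stayed beyond all random lists in each of the 6 alternatives run. Since the lists were drawn mostly from these classes with opposite leans, those ranks mirror each other and add no separate support. When centred on Osconst, the count of OsSC features at least 2-fold higher in leaf went from 9 to 32, that of Osconst features higher in leaf from 2 to 11, and that of OsL features higher in cells from 25 to 9. The signs of OsL38, OsL204, OsSC13 and OsSC19 held under each setting. Averaging features of 1 gene, and the preset gene lists, were not run because no feature has a gene name. No array could be left out. Signal over background is unknown, and 118 features were at or below the lower quartile of both arrays.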

Other observations

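All tests in this part were chosen after the data were seen.

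The difference between the samples was related to the number in the identifier. The Spearman correlation of number and difference across OsL features was -0.51 (bootstrap interval -0.58 to -0.43). In OsSC, where the differences were mostly negative, the correlation was 0.25 (0.16 to 0.34). In both classes the difference thus tended to shrink towards 0 as the number grew, though not steadily over the sets of consecutive numbers. In Osconst the number followed the level on both arrays (-0.58 in leaf and -0.57 in cells) and showed little relation to the difference (-0.10, interval -0.33 to 0.13). A candidate explanation is technical: features with high numbers may be dimmer on both arrays, which would pull their ratios towards 1. The level on the array where each class was brighter did fall with number. The correlation was -0.40 (interval -0.48 to -0.31) on the leaf array for OsL and -0.31 (-0.39 to -0.22) on the cell array for OsSC. For OsL, the level on the cell array rose with number (Spearman 0.17, interval 0.08 to 0.26), which argues against dimming on both arrays as the whole account. Features dim on both arrays were more frequent among high numbers, 52 of 219 against 16 of 219 in OsL and 29 of 242 against 18 of 242 in OsSC. Leaving them out kept a correlation with the difference of -0.53 over 370 OsL features (interval -0.61 to -0.45) and 0.22 over 437 OsSC features (0.13 to 0.31), so they are not the whole account in either class. For OsSC, the level on the leaf array had a correlation of -0.067 with number (interval -0.16 to 0.03). Median leaf intensity was 431.1 in the OsSC set with the lowest numbers and 551.3 in the set with the highest. Between them it was uneven, from 1520 in the third set to 338.9 in the seventh. The set medians thus showed no steady dimming in leaf, but the interval includes a slight one, so it stays open. An ordering of the identifiers by tag abundance or by the contrast between leaf and cells would also give such trends, and it was not tested, since no tag counts were used here.

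The Osconst features lay lower on the leaf array than on the cell array, with a median of -0.74 (bootstrap interval -0.89 to -0.51). A brightness-dependent offset between the arrays stays open: removing a loess curve left the Osconst median at -0.25 (interval -0.49 to -0.10), at percentile 6.9 of random lists, and the curve was fitted mostly to OsL and OsSC features, so what it removed depends on their mix. A single scale factor between the arrays could also account for the lean. The median difference was -0.74 in both the brighter and the dimmer 39 features, a gap of -0.0079, but its interval from -0.31 to 0.61 was too wide to decide. The 118 features dim on both arrays had a median difference of 0.061, and the array minima differed by 0.39 towards leaf, which is not the direction of such a factor, but values at the floor may follow background instead. A truly higher expression of these transcripts in cultured cells stays open and untested, because sample and array cannot be told apart with 1 array each.

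Against the lean of their class, 25 OsL features were at least 2-fold higher in cells and 9 OsSC features at least 2-fold higher in leaf. They sat late in the numbering: 22 of the 25 and 8 of the 9 had numbers above the middle of their class. Since class differences shrank towards 0 with number, this largely restates that trend and is not a separate observation. Signals near the floor could produce such features, and 0 of the 34 lay at or below the lower quartile of both arrays. That count says little, because only 7 of the 118 features dim on both arrays were at least 2-fold apart in either direction. With values under the lower quartile raised to it, 32 of the 34 stayed at least 2-fold apart, 23 in OsL and 9 in OsSC. Most of the 34 had both values above the lower quartile of their array, so this step could not change them and that count was largely fixed beforehand. Being above it on both arrays, those features were not near the floor, which argues against the floor as the whole account. Noise at higher signal stays open without a replicate. Centring on the Osconst median left 9 of the 25 OsL features and all 9 OsSC features at least 2-fold apart. That shift raises all differences alike, so it can only lower the OsL count and must keep the OsSC features. The outcome therefore says nothing for or against an offset between the arrays.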
